A study of Homo sapiens with 6 samples.

How the data were processed

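U87MG is an established human glioblastoma cell line. Per the labels' protocols, the cells received a pool of control siRNA or of siRNA against HuR for 48 h and were then kept at 1% oxygen for 24 h. HuR is the RNA-binding protein encoded by ELAVL1. Lysates were separated by ribosome density into a free/monosome, an oligosome and a polysome fraction, and RNA of each fraction was sequenced from stranded mRNA libraries. The 2 siRNAs and 3 fractions give 6 groups with 1 library each. Both siRNA conditions were hypoxic, so no comparison with normal oxygen was made here.

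Per the submitters' processing notes, the tools were bcl2fastq, STAR 2.5.0, Cufflinks 2.2.1 and Cuffnorm, and the genome build was GRCh38. The notes name no order or settings, and the annotation used for counting is not given in the sources used here. The deposited values are FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, in 1 table with 11137 loci and a column per library. A locus carries a position and the names of the genes in it. The lowest row maximum was 3.00 FPKM, so loci below about 3 FPKM in all 6 libraries are not analysed here. The rows stand in falling order of the polysome to free/monosome ratio after HuR siRNA divided by that after control siRNA (100% of neighbouring rows).

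Names were looked up in GENCODE release 29, which held 13080 of the 13093 names. The other 13 were whole numbers, as a spreadsheet makes of names that look like dates. A locus was used as a gene where exactly 1 of its names was protein-coding, which held for 8340 loci, and 82 repeats of a name were left out in favour of the locus with the highest mean. A further 842 loci joined several protein-coding genes, 1394 held noncoding names only and 561 had no name. This assignment was set after the layout of the table was seen. Some loci are much wider than the annotated gene, so that a value may include signal outside it: 3316 of the 8249 genes analysed lie in loci over 1.5 times as wide. The position may also only be that of a larger block, since for 2585 of these another locus with another name carries the same one, as with MMP1 and MMP3.

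FPKM values are not counts, so no count model was used. With 1 library per group there is no replicate, no spread between replicates and no p-value, and every difference below describes these libraries. Steady-state mRNA was taken as the sum of FPKM over the 3 fractions, after the series' own definition, and compared as log2((HuR siRNA + 1)/(control siRNA + 1)). This sum weights the fractions equally whatever amount of RNA each held. Translation efficiency (TE) was the polysome value over the free/monosome value, as log2((polysome + 1)/(free/monosome + 1)), and the TE difference was HuR siRNA minus control siRNA. Folds are on this scale with a pseudocount of 1 FPKM, which understates the differences of low genes. Genes entered with a mean of at least 1 FPKM over the 6 libraries, which kept 8249 genes. Genes were counted at log2 differences of at least 1 either way, and list members at 0.58 (1.5-fold).

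These definitions, the thresholds, 22 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The lists cover glycolysis, other HIF targets, HuR targets known in the literature, the ELAV family, immediate early and cytokine mRNAs, cytosolic ribosomal proteins, other TOP mRNAs (with a 5′ terminal oligopyrimidine tract), translation initiation factors, RNA-binding proteins of 3′ UTRs, the integrated stress response, ER chaperones, oxidative phosphorylation, mitochondrial-encoded mRNAs, long noncoding RNAs, S phase, mitosis, p53 targets, the interferon response, extracellular matrix, cholesterol synthesis, cytoskeleton and the tricarboxylic acid cycle. Markers of astrocyte-like glia, neurons, oligodendrocytes, endothelium and leukocytes were listed as well. A list's median was placed among the medians of 10000 random lists of the same size matched on mean FPKM in 20 bins, and is called outside below percentile 2.5 or above 97.5. Of 20 lists with at least 3 measured members, 1 would lie outside by chance in each measure if list members varied independently. The random lists hold unrelated genes, whereas members of a list may vary together. More lists could then lie outside without any effect of HuR. No member of the mitochondrial-encoded list was analysed here.

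Named genes are ELAVL1 and its paralogs, the 10 highest and 10 lowest steady-state differences among genes with a mean of at least 5 FPKM and the same sign in all 3 fractions, the 10 highest and 10 lowest TE differences among genes whose sign held with the oligosome value added to the polysome value, and up to 4 members per list, the 2 highest and the 2 lowest. For glycolysis any member could be named. Genes with a near-identical copy are given as uncertain. Counts of AUUUA were taken in the annotated 3′ UTR of the principal transcript.

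The depth of the libraries is unknown because the table holds no counts. The modal ratio of low values gives the worth of a single fragment in one library against another. It was 1.21 for control polysome over control oligosome (30 of 138 loci under 0.3 FPKM in both), 0.833 for HuR siRNA over control siRNA oligosome (14 of 90) and 0.694 for HuR siRNA over control siRNA polysome (36 of 398). For free/monosome it was 1.43 but rested on 5 of 57 loci, and the modal shares are low in each comparison, so these ratios are rough and no interval was computed. A 0 in the table can be a failed estimate. VIM is listed at 0 in control oligosome beside 4391 FPKM in the HuR siRNA oligosome library. Such values were kept in the counts and lists.

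The computations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data for the same 8249 genes with noise of SD 0.2 (log2) per library and 200 genes given known differences. For steady state, 100% of genes raised by log2 1.5 and 96.0% of those lowered by 1.5 were counted, against 0% of unchanged genes. For TE the shares were 90.0%, 80.0% and 0.435%. The noise of these libraries is unknown without replicates, and the simulation used under Results assumes an SD of 0.4. These shares are therefore not error rates of the genes counted below. Random lists of 20 unshifted genes lay outside in 7.0% of draws for steady state and 5.5% for TE. Alternatives varied the pseudocount, the filter, the scaling, the TE definition, the fractions summed, the threshold and the list statistic. Merged loci, a limit on locus width, the leaving out of genes listed at 0 and random lists matched on TE or transcript length were added after seeing the data.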

Results

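The series asks which mRNAs depend on HuR for their abundance and their translation in hypoxic U87MG glioblastoma cells. RNA from the free/monosome, oligosome and polysome fractions of a density gradient was sequenced after control siRNA and after HuR siRNA, with 1 library per group and 6 in all. The median FPKM of all loci was 7.02, 8.22 and 9.05 in the control free/monosome, oligosome and polysome libraries and 7.24, 8.08 and 8.91 after HuR siRNA. Loci without a protein-coding name held 12.0% of the summed FPKM in control free/monosome and 5.27% in control polysome, and 15.9% and 4.93% after HuR siRNA. No group has a replicate, so no difference below could be set against the spread between replicates, and the percentiles describe these libraries only. The 3 fractions of a gradient are not replicates either.

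HuR mRNA was lower in each fraction of the cells that received HuR siRNA. ELAVL1, which encodes HuR and lies at chromosome 19, positions 7958579 to 8005659 (GRCh38), stood at 7.68 FPKM in the control free/monosome library and 3.14 after HuR siRNA. In the oligosome fraction it was 8.53 against 2.22 FPKM, and in the polysome fraction 17.6 against 4.38 FPKM. The sum over the fractions was 33.8 FPKM in control and 9.74 FPKM after HuR siRNA, 28.8% of control, a log2 difference of -1.70. The labels and the targeted gene therefore point the same way. Among the neuronal paralogs, ELAVL3 was found only in a locus merged with other genes, and ELAVL2 and ELAVL4 are not analysed here.

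**Figure D1:**
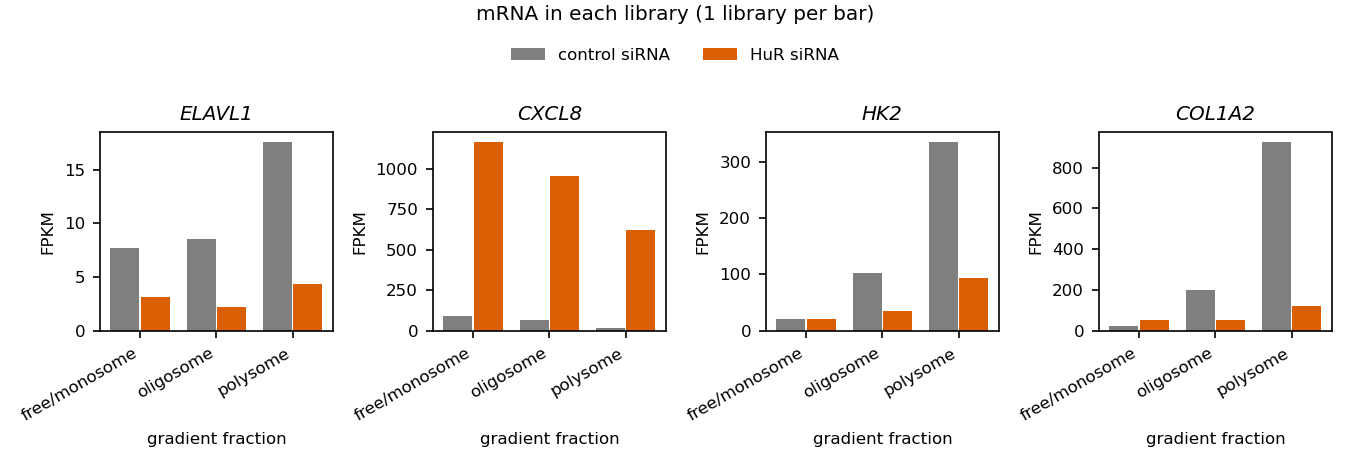
FPKM of ELAVL1, CXCL8, HK2 and COL1A2 in each gradient fraction (x axis) after control siRNA (grey) and HuR siRNA (orange), 1 library per bar and no error bars. ELAVL1 is lower after HuR siRNA in the 3 fractions, CXCL8 is higher in the 3 fractions, and HK2 and COL1A2 are lower in oligosome and polysome but not in free/monosome.

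In hypoxic control cells, most matrix mRNAs and most HIF target mRNAs were richer in polysome than in free/monosome, and ribosomal protein mRNAs were mostly richer in free/monosome. At 1.5-fold the polysome value was higher for 23 of 28 matrix genes (2 lower), 20 of 28 other HIF targets (6 lower) and 14 of 16 glycolysis genes (0 lower). The median log2 TE was 3.40 for the extracellular matrix list, 2.30 for ER chaperones, 2.27 for other HIF targets and 1.97 for glycolysis, against 0.74 for all genes. Each of these lay above the range of matched random lists, as did RNA-binding proteins of 3′ UTRs (1.58), HuR targets of the literature (1.15) and cytoskeleton (0.49). Cytosolic ribosomal protein mRNAs had a median of -4.88 and long noncoding RNAs one of -3.36, both below that range. At 1.5-fold, 10 of 13 long noncoding RNAs were lower in polysome and 3 higher. MALAT1, a noncoding RNA, had 846 FPKM in polysome and 213 FPKM in free/monosome, so a high ratio alone does not show translation. Longer transcripts had higher control TE across genes (r 0.51 with log length). These random lists were not matched on length, so a part of length in these places was not tested. COL1A2, a chain of type I collagen, had 927 FPKM in polysome and 22.3 FPKM in free/monosome. RPL27, a protein of the large ribosomal subunit, had 294 FPKM in polysome and 20780 FPKM in free/monosome. After HuR siRNA the medians lay closer together, at 1.20 for matrix, 1.14 for ER chaperones, 1.26 for other HIF targets, 0.90 for glycolysis, -3.95 for ribosomal proteins and -3.15 for long noncoding RNAs. Scaling each library to a common median moves the median of all genes from 0.74 to 0.29 in control and from 0.54 to 0.15 after HuR siRNA, so TE levels are relative.

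The highest steady-state differences after HuR siRNA included those of several cytokine genes. PI3, which encodes the elastase inhibitor elafin, was 44.5-fold higher, with a sum of 809 FPKM against 17.2 FPKM. The chemokine gene CCL20 was 24.2-fold higher and CXCL8, the gene of interleukin 8 on chromosome 4 at positions 73740506 to 73743716, was 15.6-fold higher at 2739 FPKM against 175.1 FPKM. CSF2, the gene of GM-CSF, was 12.6-fold higher and IL1B, which encodes interleukin 1 beta, was 10.6-fold higher. CSF3, the gene of G-CSF, was 11.1-fold higher in a locus 81.4 times as wide as the annotated gene, and the collagenase gene MMP1 was 7.84-fold higher in a locus 11.8 times as wide. SERPINB4 (10.8-fold), CXCL3 (9.46-fold) and CXCL2 (7.26-fold) are uncertain because each has a near-identical copy.

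The fixed list of immediate early and cytokine mRNAs, which carry AU-rich 3′ UTRs, had a median log2 difference of 1.18, above the medians of the 10000 random lists. Of its 24 measured members 16 were at least 1.5-fold higher, 2 were lower and 6 lay between. The AP-1 gene JUNB (-0.85) and the chemokine gene CCL2 (-0.60) were the lower ones. DNA replication and mitosis mRNAs were moderately higher. The S phase list had a median of 0.56 with 9 of 18 members higher and 0 lower, from MCM3, a subunit of the replicative helicase, at 0.00 to CDC6, which loads that helicase, at 1.00. The mitosis list had a median of 0.51 with 9 of 23 higher and 0 lower, from the kinesin gene KIF20A at 0.02 to ECT2, a regulator of cytokinesis, at 1.16. The integrated stress response list had a median of 0.30, with 6 of 19 higher and 2 lower. Its highest members were CHAC1, which degrades glutathione (1.32), and CTH, an enzyme of cysteine synthesis (1.28), and its lowest were STC2 (-0.90) and NUPR1 (-0.65). These lists lay above the range of random lists.

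The lowest steady-state differences were those of genes with varied functions, and no shared function was tested for them. SCG2, which encodes secretogranin II, was 8.61-fold lower, at 2.38 FPKM against 28.1 FPKM. ADA, the gene of adenosine deaminase, was 8.24-fold lower, IGFBP5, which encodes a binding protein of insulin-like growth factors, 7.93-fold lower, and SLC1A3, the gene of a glial glutamate transporter, 6.65-fold lower. AFAP1L2 was 6.66-fold lower, ACP5, the gene of an acid phosphatase, 5.55-fold lower, the selenoprotein gene SELENOM 5.47-fold lower, and LGALS3, which encodes galectin 3, 5.36-fold lower at 1679 FPKM against 9005 FPKM. USP41 was 7.55-fold lower and is uncertain because of its near copy USP18. The positions given for SCG2 (12.9 times the width of the gene), IGFBP5 (13.7), ACP5 (13.7), USP41 (6.58), ADA (3.68) and SLC1A3 (2.90) are wide. TCL1B was 7.15-fold lower in a locus 11.5 times as wide as the gene, with nearly all of its control signal in free/monosome (57.7 FPKM against 0.30 FPKM in polysome).

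Glycolysis mRNAs were lower as a group. The median log2 difference was -0.83 (percentile 0.05), with 11 of 16 measured members at least 1.5-fold lower, 0 higher and 5 between. ALDOC, an aldolase gene in a locus 45.7 times as wide as the gene, was at -1.78, HK2, the hexokinase gene induced in hypoxia, at -1.61, and the glucose transporter genes SLC2A1 and SLC2A3 at -1.54 and -1.40. LDHA, whose product makes lactate, was at -0.55, PKM, the gene of pyruvate kinase, at -0.69, and ENO1, the gene of an enolase, at -0.86. SLC16A1, the gene of a lactate transporter, was at 0.26. In merged loci, that of ALDOA was at -1.17, that of PGK1 with ATP7A at -0.96 and that of LDHB at -0.01. GAPDH is not analysed here. Restricting loci to 1.5 times the annotated width left 8 members and a median of -0.62, at percentile 6.23 and so no longer outside.

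Other hypoxia-induced mRNAs and those of the secretory pathway and matrix were lower too. The list of other HIF targets had a median of -0.63 (percentile 0.18), with 15 of 28 members lower and 0 higher, among them the collagen prolyl hydroxylase gene P4HA2 (-1.51) and the lysyl oxidase gene LOX (-1.43). EGLN1, the gene of the oxygen sensor PHD2, was at 0.07 and WSB1 at 0.30. ER chaperones had a median of -0.70 (percentile 0.04), with 10 of 18 lower and 1 higher. Calreticulin mRNA (CALR) was at -1.69 and that of the chaperone HSP90B1 at -1.37, against XBP1, a transcription factor of the unfolded protein response, at 0.76. The matrix list had a median of -1.20, below the 10000 random lists, with 19 of 28 lower and 3 higher. COL1A2 (-2.32) and TGFBI (-2.18), which encodes a matrix adhesion protein, were lowest, while the metalloproteinase genes MMP1 (2.97) and MMP3 (4.61-fold higher), which are given the same wide position, were highest. Leaving out the polysome library ended the call for other HIF targets (percentile 4.49), ER chaperones (23.0) and matrix (-0.47, percentile 5.26), and so did the limit on locus width for other HIF targets (3.09) and ER chaperones (6.88).

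Across all 8249 genes, 158 were at least 2-fold higher and 520 at least 2-fold lower in steady state, with a median of -0.11. The sign was the same in all 3 fractions for 155 of the higher genes (98.1%) and 377 of the lower genes (72.5%). Of all genes 44.4% had the same sign in all 3. The other lower genes did not go down in every fraction. Other TOP mRNAs had a median of -0.13 (percentile 99.7, since matched genes were lower still), which moved to -0.17 and percentile 26.5 without the free/monosome library. EIF4B (-0.80) and EIF3E (-0.72), genes of initiation factors, were its lowest members, EEF1B2 (0.15), an elongation factor gene, was among its highest, and VIM counts in this list and in the cytoskeleton list despite its 0. Without genes listed at 0 the medians were -0.18 (percentile 98.8) and -0.26 (86.6). The remaining lists lay inside the random range: ribosomal proteins -0.46 (22 of 67 lower, 0 higher), oxidative phosphorylation -0.51 (12 of 28 lower, 0 higher), cytoskeleton -0.19, p53 targets 0.11, cholesterol synthesis -0.01, RNA-binding proteins -0.10, initiation factors -0.06, long noncoding RNAs -0.25, interferon response -0.29 and the tricarboxylic acid cycle -0.32. The lower values of ribosomal proteins and oxidative phosphorylation rest on the free/monosome library, since without it the medians were 0.06 (percentile 99.8, above the random range) and -0.07.

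**Figure D2:**
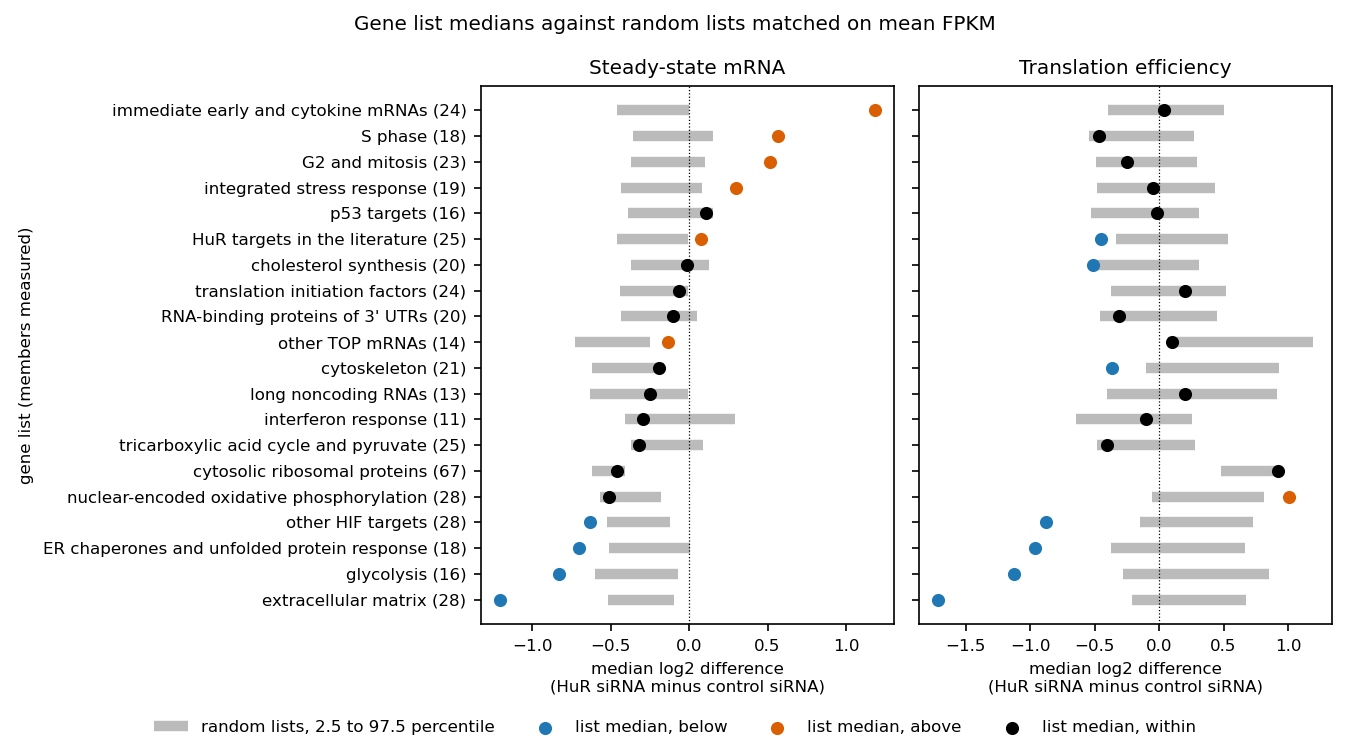
Median log2 difference (HuR siRNA minus control siRNA) of each gene list in steady-state mRNA (left) and TE (right), with the number of measured members in brackets. Grey bars span the central 95% of 10000 random lists matched on mean FPKM, and points are blue below, orange above and black within them; cytokine mRNAs reach 1.18 in steady state and matrix mRNAs -1.71 in TE.

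HuR targets known in the literature went both ways in steady state. Of 25 measured members 9 were at least 1.5-fold higher, 4 were lower and 12 lay between, with a median of 0.08 (percentile 99.7). CXCL8 (3.96) and IL6, the interleukin 6 gene (2.48), were highest, and PLAU, the gene of urokinase (-0.95), and TGFB1 (-0.86), the gene of transforming growth factor beta, were lowest. VEGFA, the gene of the angiogenic factor, was at -0.52, and was singled out after its values were seen. The call ended without the free/monosome library (percentile 90.7) and with merged loci included (95.6). Of the higher members, CXCL8, IL6, PTGS2, FOS and MYC also belong to the immediate early and cytokine list. CCNA2 also belongs to the mitosis list and EIF4E to the initiation factors, so the lists are not separate results.

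Genes with more AUUUA pentamers, the core of AU-rich elements, were less low in steady state. Genes with 0 pentamers in the annotated 3′ UTR had a median of -0.24 (2451 genes), those with 1 to 2 one of -0.13 (2264), those with 3 to 5 one of -0.06 (1476) and those with 6 or more one of -0.02 (1997). Longer 3′ UTRs hold more pentamers, so genes were also compared within 10 classes of 3′ UTR length. Matching on mean FPKM had been planned but was not done, so a part of expression level in these differences was not tested. Genes in the upper 25% of pentamer counts lay above those in the lower 25% in 10 of 10 classes, by a median of 0.15 (range 0.01 to 0.21). For TE the medians were -0.14, -0.19, -0.14 and -0.09 in the same order, and the difference within length classes was 0.21, with the same sign in 8 of 10.

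TE of matrix mRNAs was far lower after HuR siRNA, and that of oxidative phosphorylation mRNAs was higher. COL1A2, on chromosome 7, had a polysome to free/monosome ratio of 41.5 in control and 2.27 after HuR siRNA, a log2 TE difference of -4.14, in a locus 4.22 times as wide as the gene. COL6A1 (-3.65, in a locus 15.5 times as wide as the gene), COL5A1 (-3.26) and COL1A1 (-3.21), genes of other collagen chains, FN1 (-3.22), which encodes fibronectin, MRC2 (-3.12), the gene of a collagen receptor, and SEZ6L2 (-3.01) were also among the lowest. On the other side stood COX7B (2.47), UQCRB (2.31) and COX5B (2.12), genes of respiratory chain subunits, ATP5IF1 (2.19), the gene of the ATP synthase inhibitor, DNAJC15 (2.17), a mitochondrial chaperone gene, GLRX (2.15), the glutaredoxin gene, and TPRKB (2.24). COX7B, in a locus 49.8 times as wide as the gene, had 160 FPKM in polysome and 2172 FPKM in free/monosome in control, and 365 and 886 FPKM after HuR siRNA.

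Of the other genes at either end, RHOT1 and ARHGAP30 are listed at 0 in the HuR siRNA polysome library, beside 1.55 and 3.90 FPKM in control polysome, in loci 1.70 and 7.11 times as wide as the gene. TIPIN (-3.21), in a locus 2.14 times as wide, differed in free/monosome, at 71.7 FPKM against 6.77 FPKM, with polysome values of 4.95 and 4.90 FPKM. TCL1B (3.02) had polysome values of 0.30 FPKM in control and 0.29 FPKM after HuR siRNA. C5orf51 (2.53), in a locus wider still than that of ARHGAP30 relative to its gene, had a polysome to free/monosome ratio of 0.441 in control and 3.24 after HuR siRNA. In all, 747 genes had a TE at least 2-fold higher after HuR siRNA and 920 at least 2-fold lower, with a median of -0.14. With the oligosome value added to the polysome value the counts were 286 higher (267 of them among the 747) and 685 lower (654 among the 920), and with it added to free/monosome 486 (474) and 315 (288).

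The spread of TE over genes was narrower after HuR siRNA, and the gene groups moved with it. The SD of log2 TE was 1.85 in control and 1.33 after HuR siRNA. The correlation across genes, which are not independent replicates, between the mean log2 TE of both conditions and the TE difference was -0.68. It follows from the unequal SDs and is no separate evidence. A simulation without effect and an assumed noise SD of 0.4 (log2) gave 0.01, but it sets equal spread in both conditions, which fixes a value near 0. Genes high on polysomes in control were lower by this measure after HuR siRNA, and genes low on polysomes higher. For this reason each list below is also set against random lists matched on mean FPKM and on that mean log2 TE, a comparison added after seeing the data.

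**Figure D3:**
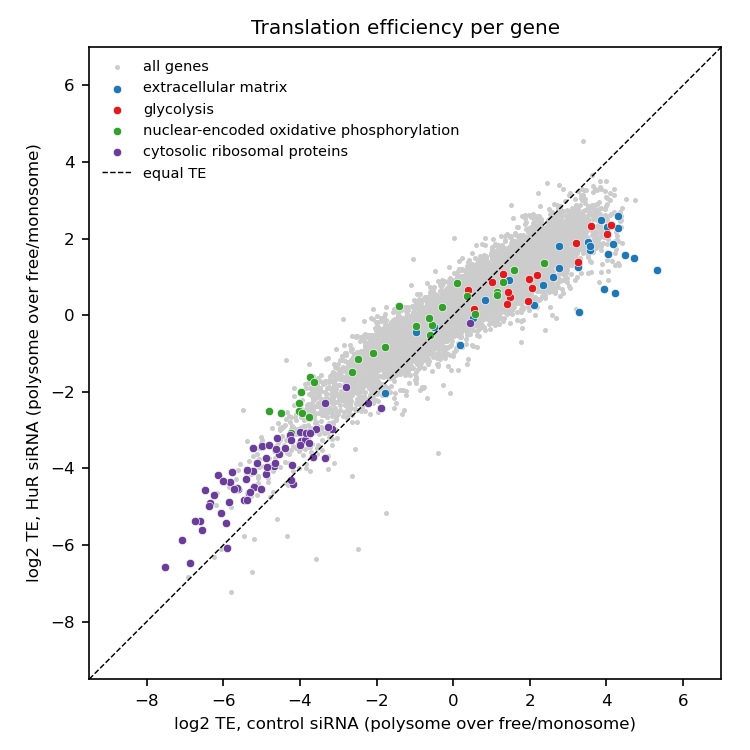
Log2 TE (polysome over free/monosome, FPKM + 1) of 8249 genes after control siRNA (x axis) and HuR siRNA (y axis), with 4 gene lists in colour and equal TE as a dashed line. Matrix and glycolysis genes lie mostly below the line at high TE, and ribosomal protein and oxidative phosphorylation genes mostly above it at low TE; the SD is 1.85 along x and 1.33 along y.

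Glycolysis mRNAs had lower TE after HuR siRNA, beyond what genes of like TE showed. Their median TE difference was -1.12, with 12 of 16 members lower, 0 higher and 4 between, below the 10000 random lists. HK2 went from a polysome to free/monosome ratio of 16.8 to 4.50 (log2 TE difference -1.89), SLC2A1 had 1219 FPKM in control polysome and 322 FPKM after HuR siRNA, and PFKFB3, the gene of a regulator of phosphofructokinase, was at -1.76 and SLC2A3 at -1.58. LDHA (-0.15), PGAM1 (-0.24), PKM (-0.37) and TPI1 (0.25) lay between. Random lists of like TE had a median of -0.55, and glycolysis stood at percentile 0.11 of them. By fraction, the list median was -0.22 in free/monosome, -0.86 in oligosome and -1.13 in polysome.

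The matrix, ER and HIF lists were lower in TE as well. Matrix mRNAs had a median of -1.71 with 22 of 28 lower and 0 higher, below both kinds of random lists (percentile 0.00 of those of like TE), and LAMA4 (0.54), a laminin gene, and CD44 (0.20), a hyaluronan receptor gene, were highest. ER chaperones had a median of -0.97 with 11 of 18 lower and 2 higher (percentile 0.60 of lists of like TE). The chaperone genes HSPA5 (-1.99) and HSP90B1 (-1.82) were lowest, and SDF2L1 (0.89) and MANF (0.83) highest. Other HIF targets had a median of -0.88 with 17 of 28 lower and 7 higher, and were no longer outside among lists of like TE (percentile 3.61). CA12 (-1.69), a carbonic anhydrase gene, was among the lowest, and FAM162A (1.34) and BNIP3L (1.15), nuclear genes of mitochondrial proteins, were highest. Matching on control TE alone gave percentiles of 0.54 for glycolysis, 0.01 for matrix and 13.2 for ER chaperones.

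Oxidative phosphorylation mRNAs had higher TE, with a median of 1.01 (percentile 99.8; 99.9 among lists of like TE), 17 of 28 members higher and 2 lower. Lower free/monosome values made up more of this than higher polysome values. The list median was -0.56 in free/monosome, -0.27 in oligosome and 0.22 in polysome, each within the random range. Matched random lists had a median of -0.37 in free/monosome, so lower values there were not particular to this list. The members with lower TE were SDHA (-1.01) and ATP5F1B (-0.61). Ribosomal protein mRNAs had a median of 0.92 with 51 of 67 higher and 1 lower, within the random range (percentile 94.7). Among lists of like TE, whose median was 1.07, they stood at percentile 2.84, so their higher TE was no more than that of other poorly loaded mRNAs. RPL27 (1.95) and RPL34 (1.91) were highest, and RPL3 (-0.65) and RPLP0 (-0.53) lowest.

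HuR targets of the literature had a median TE difference of -0.45 with 8 of 25 lower and 4 higher (percentile 0.58), but stood at percentile 42.2 among lists of like TE. PLAU (-1.53) and NCL (-0.99), the nucleolin gene, were lowest, and CXCL8 (1.38) and PTMA (1.17), the prothymosin gene, highest. Cytoskeleton mRNAs were at -0.36 (percentile 0.31; 1.61 among lists of like TE), from FLNA, the filamin A gene (-2.03), to MYL12A, a myosin light chain gene (1.61). Cholesterol synthesis was at -0.51 (percentile 2.36; 11.2 among lists of like TE), from FDFT1, the gene of squalene synthase (-1.44), to STARD4, the gene of a sterol carrier (1.35). The other lists lay inside the random range of TE, with medians of 0.04 for immediate early and cytokine mRNAs, 0.10 for other TOP mRNAs (percentile 3.07; 1.41 among lists of like TE, whose median was 0.59), -0.05 for the integrated stress response, -0.25 for mitosis, -0.47 for S phase, -0.01 for p53 targets, -0.10 for the interferon response and 0.20 for long noncoding RNAs. Without the loci over 1.5 times the annotated width the calls for HuR targets (percentile 12.2) and cytoskeleton (13.4) ended.

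Steady state and TE were only loosely related across genes. Pearson's r was 0.16, against 0.10 in that simulation, and the covariance was 0.0716 against 0.0329, both of which depend on the assumed noise SD of 0.4. At 1.5-fold, 684 genes were lower in both, 423 lower in steady state with higher TE, 67 higher in steady state with lower TE and 106 higher in both. HK2 and COL1A2 are among the first of these, COX5B (-1.09 in steady state, 2.12 in TE) among the second, and CXCL8 (3.96 and 1.38) among the last.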

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

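The tests of material carried between fractions, of the interferon list and of the leukocyte markers were chosen after the results were seen; those of transcript length and of glycolysis against genes of like TE were written down before their values were computed, although the lists of like TE were added after seeing the data.

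Matrix mRNAs moved by their median in opposite directions in different parts of the gradient, which is what marked them for a closer look. Their median log2 difference between HuR siRNA and control siRNA was 0.47 in free/monosome and -1.51 in polysome, both outside matched random lists. At 1.5-fold, 11 of 28 members were higher, 3 lower and 14 between in free/monosome, and 3 were higher and 22 lower in polysome. The difference between the fractions was not tested, as each has 1 library per siRNA. For COL1A2 the free/monosome value was 54.0 FPKM against 22.3 FPKM in control, and the polysome value 122.9 FPKM against 927 FPKM.

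The narrower range of TE after HuR siRNA (SD 1.33 against 1.85) may be technical. Transcript length bias as the whole cause is argued against: within 10 length classes of 5899 genes the ratio of the SDs was still 0.72 (range 0.68 to 0.87). Longer transcripts did have lower TE differences across genes (r -0.41 with log length), so a part of length in them stays open. Polysomal material in the HuR siRNA free/monosome library stays open: genes above a mean log2 TE of 2 were also lower in polysome, by a difference of -0.41 from all genes, but the value depends on how they are chosen (-0.47 on control TE, -0.21 on HuR siRNA TE, -0.25 without any polysome value) and did not hold past the bound of 0.3. Free/monosome material in the HuR siRNA polysome library is left open too. Loci without coding genes had a smaller TE gain than genes of equal control TE, by a difference of -0.39 (SE 0.06, below 0 in 9 of 9 TE classes). This passed the bound of 0.3 written for it, but by less than 2 SE, a margin which that bound did not include. Over the classes the difference ran from -0.60 to -0.03. A general effect of HuR loss on polysome loading also stays open, as siRNA and gradient cannot be told apart with 1 gradient per siRNA.

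The lower TE of glycolysis mRNAs is not accounted for by the narrower range alone, as the list stood at percentile 0.11 of lists of like TE and mean FPKM. The median of those lists was -0.55, so a part of the -1.12 may come with the range. An effect of HuR on these mRNAs is a hypothesis that remains, beside any difference between the gradients that strikes this group.

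Higher cytokine mRNAs after HuR siRNA could be a response to transfected RNA. The measured part of the interferon list (11 of 22 members) speaks against an interferon response as its cause: 0 of 11 members were at least 1.5-fold higher. The median steady-state difference was -0.29 (-0.46 to 0.11 over the alternatives, with 0.11 where the mean had to be at least 5 FPKM). Both conditions received an siRNA pool, so a response shared by both would not show here. Members ran from IFI27 at -1.88 and IFIT1 at -1.46 to IFI44L at 0.39. RNA of leukocytes could not be tested, since of 6 markers only CSF1R was measured (-0.91), and the cells are a pure line by their label. Other innate responses to the siRNA pool were not tested and stay open beside an effect of HuR.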

How the results depend on the processing

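The limit on locus width, merged loci, leaving out genes listed at 0, lists of like TE or length, and the gene groups watched most closely here were chosen after the data were seen; the other alternatives were planned. HuR mRNA was lower in all 6 alternatives run (-1.83 to -1.44). Of the gene list values, 211 of 240 in steady state and 201 of 257 in TE kept their side of the random range and of its middle. The cause of each difference below was not tested except where fewer genes enter. At 1.5-fold, 645 genes were higher and 1533 lower in steady state, and 1584 and 2182 in TE. A pseudocount of 0.1 FPKM gave 1403 genes with lower TE (916 of the 920 among them), a mean of at least 5 FPKM left 101 higher in steady state, and the mean of the 3 log2 folds left 231 lower. With oligosome added to polysome 286 genes had higher TE, and with it added to free/monosome 486 higher and 315 lower. Loci at most 1.5 times the annotated width (4933 genes) gave 100 higher and 317 lower in steady state, 401 and 575 in TE, -0.62 for glycolysis in steady state (percentile 6.23) and 0.72 for ribosomal protein TE (46.9). Ribosomal protein TE had a mean of 0.84 (percentile 99.6), and its median of 0.92 fell to percentile 2.84 among lists of like mean TE and 0.15 of like control TE. Without polysome the matrix list was at -0.47 (percentile 5.26), and without free/monosome other TOP mRNAs crossed to the lower side (-0.17, percentile 26.5). Without genes listed at 0 the matrix list was at -1.33 in steady state and -1.72 in TE, both below the random lists. No filter at all gave 8258 genes, so this alternative moved almost nothing. Depth is unknown and there is no replicate. No paired test was run: the siRNAs can be paired by fraction, but fractions of a gradient are not replicates. The results come from no test.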

Other observations

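Translation initiation factors held members at both ends of the TE difference. Among 24 measured initiation factors the median TE difference was 0.20 (6 higher, 4 lower), with EIF4G1, the scaffold of the cap-binding complex, at -1.75 and EIF2S1, the alpha subunit of eIF2, at -0.86. EIF1AX (1.24) and EIF4E (0.94), the gene of the cap-binding protein, were highest, and EIF4E was also higher in steady state (0.87). Among RNA-binding proteins of 3′ UTRs the median TE difference was -0.31, with 8 of 20 lower and 0 higher (percentile 10.5; 75.9 among lists of like TE), and KHSRP (-1.33) and PTBP1 (-1.30), genes of splicing and decay factors, lowest. In the tricarboxylic acid cycle list 8 of 25 members were lower in TE and 0 higher (median -0.40, percentile 6.12; 14.0 among lists of like TE), with PC, the gene of pyruvate carboxylase, at -1.62 and OGDH, that of oxoglutarate dehydrogenase, at -1.38. In steady state FH, the fumarase gene, was at 0.65 and PC at -0.85. In the p53 list PHLDA3 was at -0.90 and PLK3 at 0.70 in steady state, and FDXR was at -1.38 in TE.

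Few markers of other cell types were measured. SLC1A3, of the astrocyte-like glia list, was at -2.73 in steady state, and the neuronal markers MAP2 and SNAP25 were at -1.15 and -0.83. No marker of oligodendrocytes or endothelium was analysed here. Loci with noncoding names only had a median log2 TE of -2.24 in control and -1.70 after HuR siRNA, and loci without a name -2.28 and -2.27. Of the long noncoding RNAs, SNHG15 was at 0.69 and SNHG1 at -0.89 in steady state. In TE, 3 of 13 were higher and 2 lower at 1.5-fold. MALAT1 (-1.12) and NORAD (-1.11) were lowest, and SNHG8 (1.17) and ZFAS1 (1.12) highest.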
